A study of Mus musculus with 18 samples.

How the data were processed

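The series holds 18 one-colour Affymetrix arrays of mouse RNA: 12 of sorted mammary tumor cells, 5 of sorted cells labelled as normal mammary epithelial cells and 1 of a commercial reference RNA. Per the labels' protocols, total RNA was isolated with a column kit and amplified in a 2-cycle T7 procedure before labelling. The deposited values are probe-set signal intensity on a linear scale, made with GCOS per the submitters' processing notes, which give no version. The mean after trimming 2% from each end was equal on every array, as measured from the deposited intensity values. The series' design text says that a reference RNA was used to normalize the samples; how is not given in the sources used here, and the deposited values are not ratios to it. Detection calls were not used here, so that genes near background are not told apart from absent ones.

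The table has 45101 probe sets on 18 arrays, of which 64 are controls. Names came from the platform annotation given with the table: 34945 probe sets have 1 gene symbol, 932 several and 9160 none; 0 symbols were updated through the reference gene table. The last 2 kinds were not named or used by gene. Each of 18193 genes was represented by its probe set with the highest mean over the arrays of the fit, and 9010 genes have over 1 probe set. Some common genes are unnamed here for this reason. No genome was used. Values were taken as log2(value + 32). The array medians on that scale lay between 6.70 and 7.09, so no further normalization was applied. The 40% of genes with the lowest mean were left out, which left 10916 genes per comparison.

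The groups came from the sample titles. Tumor comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend) on the 12 tumor arrays with 4 group means. The normal comparison used the 5 normal arrays. Tumors and normal epithelium were compared through 1 mean per tumor or preparation, without the CD24 low array. All adjusted p-values are Benjamini-Hochberg values from limma, with a threshold of 0.05. The gene lists, 25 with 425 entries of which 394 were on the array, were tested with camera at a preset correlation of 0.01, adjusted over the 21 lists with at least 3 measured genes. The lymphocyte, adipocyte and sort marker lists had 2 measured genes and the erythroid list 0, and these were not tested as lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

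The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named both sort markers in each comparison; the 10 largest changes per direction, past the threshold and of the same sign in each tumor or preparation (without overlap of the replicates in tumors against normal), in the first comparison, the normal one and tumors against normal; the 3 largest in the others; the 5 smallest p-values where none passed; and up to 4 members per list. Every gene that passed in the unblocked fits had the same sign in each tumor or preparation. Not every gene the rule takes is printed. Beyond it, keratins, Ptprc, P2ry10, Postn and Col6a3 were named after their values were seen. The rule for the largest changes was also applied to the blocked fits, with the 5 largest per direction in the comparisons other than the first.

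Arrays with the same tumor number come from the same tumor. Deviations from the group means correlated at 0.389 to 0.728 over the 18 pairs of arrays from the same tumor and at −0.458 to −0.0526 between tumors, so the numbers pair the arrays, and blocked values are printed beside the results they change. The 2 arrays of a normal preparation share its number, and their deviations correlated at 0.0543. The labels give transplant generation 1 for tumors 1 and 2 and none for tumor 7. That the tumors or preparations came from separate animals is not stated for the normal cells, so those p-values measure the spread between these samples. No 2 arrays were duplicates: the highest Pearson correlation between arrays was 0.981, between the 2 normal CD29H CD24P arrays.

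The alternatives were an offset of 1 and an offset 4 times as large, quantile normalization, a median shift, no filter, a 60% filter, the mean of the probe sets of a gene, each probe set by itself, no intensity trend, the replicate block, all 17 sorted-cell arrays in 1 fit, a random block, and leaving out each array or tumor. The actin 3'/5' ratio of each array as a covariate, with and without the block, and leaving out the 2 tumor arrays with the lowest ratios (23.2 and 14.4, both of tumor 2) were added after seeing the data. So were the CD24 effect within CD29 low cells, the CD29 effect within CD24 low cells, and an estimated correlation in the comparison of tumor CD29H CD24H with normal CD29H CD24P cells.

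The procedure was tested on simulated data made from the measured means and residual spreads of 10916 genes, with 200 genes changed by known amounts. The simulated residuals were independent between genes and, apart from a tumor shift in the blocked runs, between arrays. Measured arrays of the same tumor correlated at a median of 0.608, so the rates without the block hold for data unlike these in that respect. In the first comparison it recovered 18% of genes changed by 1 log2 unit, 52% at 2, 92% at 3 and 98% at 4, and with the block 28%, 80%, 100% and 100%. In CD29H CD24H against CD29H CD24L it recovered 4%, 54%, 82% and 92%, and with the block 28%, 88%, 96% and 100%. In the normal comparison it recovered 0%, 36%, 78% and 78%, and in tumors against normal 2%, 48%, 78% and 84%.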

Results

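Gene expression was measured on 18 one-colour Affymetrix mouse arrays. Cells of 3 mouse mammary tumors, numbered 1, 2 and 7, were sorted by the surface proteins CD29 (the integrin beta1 chain, encoded by Itgb1) and CD24 (encoded by Cd24a) into 4 populations, called here by high (H) or low (L) staining. Each tumor gave 1 array per population, so that n = 3 for each. Cells labelled as normal mammary epithelial cells gave 2 arrays of CD29 high CD24 positive cells (CD29H CD24P), 2 of CD29 positive CD24 high cells (CD29P CD24H) and 1 of CD24 low cells. On the CD24 low array the fibroblast list stood at 14.41 and the luminal list at 6.93, so its markers go against the epithelial label. One array held a commercial reference RNA. The study used the tumor arrays to look for genes of tumor-initiating cells, which are known from it to be the CD29H CD24H cells. All arrays had the same trimmed mean signal, and their medians lay between 71.6 and 104.2 signal units. The number of arrays limits the precision. Differences below are on the log2(value + 32) scale, which understates the change of dim genes, and are given with standard errors from limma.

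The sort markers themselves were compared first. Cd24a transcript differed by 0.33 ± 0.22 between the CD24 high and CD24 low tumor populations (adjusted p = 0.868 with limma), and Itgb1 by 0.82 ± 0.60 between the CD29 high and CD29 low ones (adjusted p = 0.944). Neither passed. Within CD24 low cells alone, a setting chosen after seeing the data, Itgb1 was higher in the CD29 high ones in the blocked fit (2.15 ± 0.51, adjusted p = 0.0230) but did not pass without the block (adjusted p = 0.461). Among CD24 high cells it went the other way, lower in CD29H CD24H than in CD29L CD24H cells by −0.50 ± 0.85, and did not pass with or without the block (adjusted p = 0.828 and 1). In normal epithelium Cd24a was lower in CD29H CD24P than in CD29P CD24H cells, by −1.16 ± 0.20 (adjusted p = 0.00199), and Itgb1 differed by 0.80 ± 0.32 (adjusted p = 0.0907). On the single normal CD24 low array the Cd24a signal was 845 units, against 18260 to 49680 units on the 12 tumor arrays. The tumors differed from one another in their keratins. Krt8, a keratin of luminal cells, lay between 15.15 and 15.56 on the log2 scale on the 4 arrays of tumor 7, and at most at 13.36 on those of tumor 1 and 13.10 on those of tumor 2. Krt14, a keratin of basal cells, lay between 8.34 and 8.90 in tumor 7 and was at least 11.49 in the other tumors. Over 10916 genes, the tumor of origin took a median of 38.5% of the sum of squares among the 12 arrays, and the sorted population 23.3%. The mean shares expected by chance, each factor taken alone, are 18.2% and 27.3%. These are means beside medians, and they ignore that the tumor took more than its share and left less for the population. The population share can therefore not be read as below chance.

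**Figure D1:**
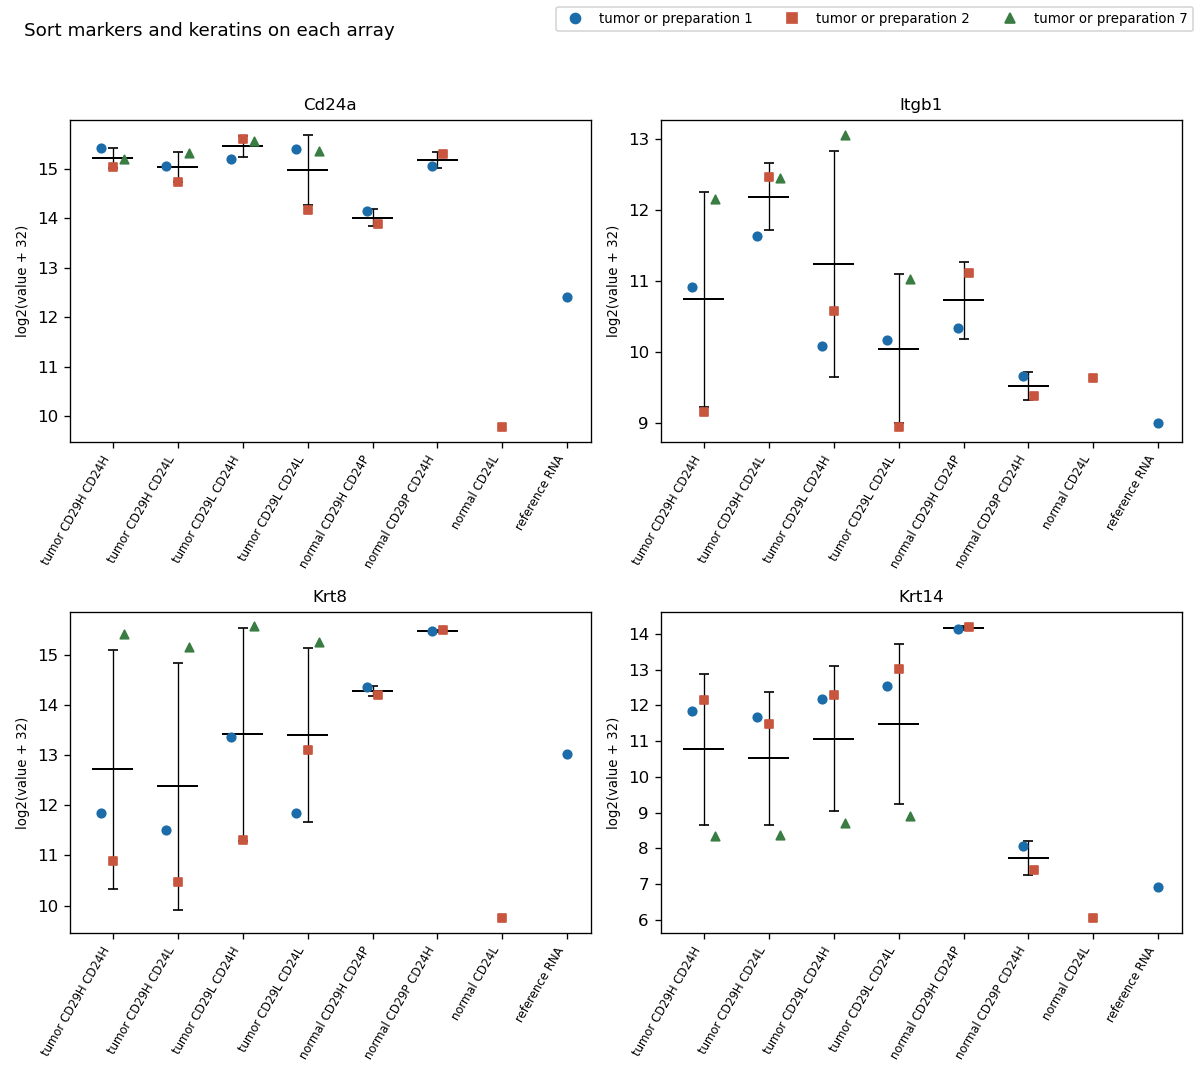
Signal of Cd24a, Itgb1, Krt8 and Krt14 on each array, as log2(value + 32), by group; points are arrays, shaped by tumor or preparation number (the reference RNA is numbered 1), and bars are the group mean with its SD where a group has over 1 array. Krt8 is above 15 and Krt14 below 9 on every array of tumor 7.

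The first comparison asked which genes set the CD29H CD24H tumor cells apart from the mean of the other 3 tumor populations. Genes of cell division were higher on balance: all 19 measured mitosis genes and 18 of 19 DNA replication genes had positive differences, with list means of 0.62 and 0.53 (adjusted p = 3.66e-07 and 9.96e-08 by camera, limma's test of a gene list against the other genes). Bub1, a kinase of the spindle checkpoint, differed by 0.99 ± 0.35, Kif20a by 0.94 ± 0.35, the replicative helicase subunit Mcm2 by 0.84 ± 0.23 and Rrm2 by 0.98 ± 0.30, and none of them passed singly. Of 37 genes of the DNA damage response and repair 32 had positive differences, with a mean of 0.31 (adjusted p = 2.73e-05). The 17 genes of the fibroblast and collagen list were all negative, with a mean of −1.46 (adjusted p = 3.27e-16), as were all 15 macrophage and myeloid genes, with a mean of −0.80 (adjusted p = 9.50e-05). Most of the fibroblast difference came from the CD29H CD24L cells. The list mean was −3.32 against these alone, −0.72 against CD29L CD24L and −0.34 against CD29L CD24H cells. Lower lists also included mesenchymal transition (mean −0.96), interferon response (−0.67), class II antigen presentation (−0.56), endothelial (−0.54) and basement membrane genes (−0.33). With an estimated correlation in place of the preset one, 0 of these 10 lists passed: adjusted p = 0.306 for mitosis, 0.0749 for DNA replication, 0.159 for repair, 0.159 for fibroblast and 0.369 for macrophage genes. The p53, Wnt, Notch, Hedgehog, epigenetic, hypoxia, hormone-sensing and alveolar lists did not pass by camera in any of the 6 tumor comparisons.

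Single genes of this comparison passed only once the tumor was taken into account. In limma's fit without it, 0 of 10916 genes passed, and 759 had an unadjusted p under 0.05. The smallest p-values belonged to Mmp23, Aar2, Thy1, Aif1l and Igfbp7, with differences of −2.10 ± 0.40, −2.02 ± 0.40, −1.89 ± 0.38, −2.90 ± 0.58 and −1.45 ± 0.30, none of which passed (adjusted p = 0.428 for each). Within the fibroblast list 11 of 17 members were lower when adjusted over the list alone, and 7 of 12 in the mesenchymal list. In the fit with the tumor as a replicate block 85 genes passed, 4 higher and 81 lower, among them 4 of the 17 fibroblast and 3 of the 12 mesenchymal genes (15 and 9 when adjusted over the list alone). The higher ones were Glrb (a glycine receptor subunit, 1.63 ± 0.29), Gtpbp10 (1.36 ± 0.25), BC055324 (1.35 ± 0.28) and Mbnl3 (1.25 ± 0.25). The lower ones included Pik3cd (−3.27 ± 0.66), Aif1l (−2.90 ± 0.42), Srr (−2.62 ± 0.57) and the T-cell costimulator Icos (−2.39 ± 0.43). The Pik3cd probe set was bright, with a mean of 14.37 in the other populations, and whether it reads leukocyte transcript was not tested. Also lower were the procollagen processing enhancer Pcolce (−2.34 ± 0.43), the collagen Col5a3 (−2.12 ± 0.37), Serping1 (−2.11 ± 0.39) and Mmp23 (−2.10 ± 0.38). The matrix genes draw on the CD29H CD24L cells, against which alone Pcolce differed by −4.50 ± 0.52 in the blocked fit. These names come from the naming rule applied to the blocked fit. The blocked count was 0 without the CD29H CD24H array of tumor 2, 0 without that of tumor 7, 0 without all arrays of tumor 7, 7 without those of tumor 2, and 26 to 256 without any other single array (the highest without the CD29L CD24L array of tumor 2).

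**Figure D2:**
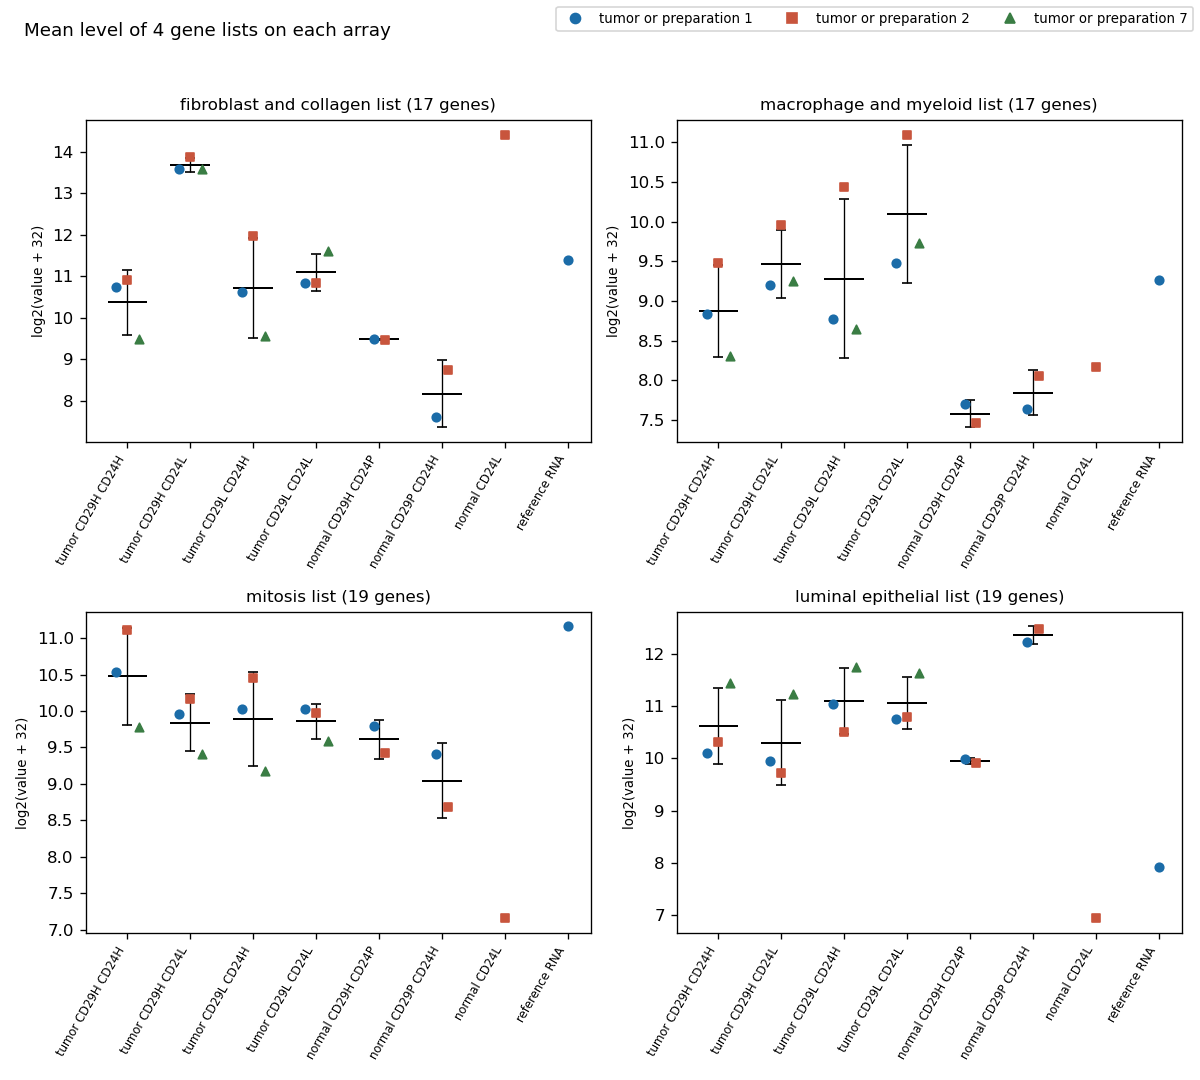
Mean of log2(value + 32) over the genes of 4 lists on each array, by group; points are arrays, shaped by tumor or preparation number (the reference RNA is numbered 1), and bars are the group mean with its SD where a group has over 1 array. The fibroblast list stands at 13.59 to 13.89 on the 3 tumor CD29H CD24L arrays and at most at 11.97 on the other tumor arrays.

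Against the CD29H CD24L cells of the same tumors, which differ in the CD24 gate, the CD29H CD24H cells had far less transcript of extracellular matrix genes. Of the 17 fibroblast and collagen genes 14 fell (17 when adjusted over the list alone), with a list mean of −3.32 (camera adjusted p = 5.05e-32; adjusted p = 0.0415 with an estimated correlation). Dpt (dermatopontin) differed by −4.89 ± 0.94, Dcn (decorin) by −4.34 ± 0.79, Col6a1 by −4.01 ± 0.78 and Fap (fibroblast activation protein) by −3.83 ± 0.55. Of 12 mesenchymal transition genes 7 fell (8 when adjusted over the list alone; list adjusted p = 0.0183 with an estimated correlation), among them Cdh11 (−3.74 ± 0.63), Sparc (−3.71 ± 0.60), the transcription factor Zeb1 (−3.25 ± 0.65) and fibronectin, Fn1 (−2.52 ± 0.40). The basement membrane genes Nid1 (−3.82 ± 0.55) and Itga1 (−1.66 ± 0.39) fell as well (list adjusted p = 0.0415 with an estimated correlation), as did Cxcl14 (−2.68 ± 0.44), Itm2a (−4.67 ± 0.76) and Pcolce (−4.50 ± 0.65). Mitosis and DNA replication genes were higher on balance, with means of 0.64 and 0.64 (adjusted p = 0.000107 and 2.65e-06; with an estimated correlation adjusted p = 0.408 and 0.0691). Other lists moved too: repair (0.43) and luminal genes (0.33) were higher on balance, and endothelial (−1.08, adjusted p = 0.000107), interferon (−0.84, 0.000884), dissociation stress (−0.47, 0.00292) and macrophage genes (−0.64, 15 of 15 negative, 0.0317) lower. Their adjusted p with an estimated correlation was 0.107, 0.589, 0.239, 0.215, 0.215 and 0.610 in that order. No endothelial gene passed over all genes, and 4 of 9 were lower in the blocked fit. Of the 21 lists 11 passed by camera, and the fibroblast, mesenchymal and basement membrane lists alone held with an estimated correlation.

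Altogether 237 genes passed in that comparison, 0 higher and 237 lower, and each of the 237 had the same sign in all 3 tumors. The blocked fit passed 538, 34 higher and 504 lower, including all 237, and all 17 fibroblast genes were among the lower. With the block and an estimated correlation together 0 lists passed. The count was 66 without the CD29H CD24L array of tumor 2, 130 without that of tumor 7, 144 without that of tumor 1 and 148 without the CD29H CD24H array of tumor 7. Leaving out a whole tumor left 1 (tumor 1), 0 (tumor 2) or 52 (tumor 7) genes, and 269 to 607 in the blocked fit with 1 array or tumor left out.

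Against CD29L CD24H cells, which differ in the CD29 gate, no single gene passed in limma (0 genes; 287 at an unadjusted p under 0.05). The smallest p-values were those of Creb3l3 (−2.11 ± 0.45), Dgkq (−1.53 ± 0.33), Aar2 (−2.16 ± 0.49), Fgfr4 (−1.92 ± 0.46) and Igha (−2.43 ± 0.60), all with an adjusted p of 1. Mitosis genes were higher on balance in CD29H CD24H cells, with 19 of 19 positive and a mean of 0.59 (camera adjusted p = 3.18e-07), and DNA replication genes with 18 of 19 and a mean of 0.51 (5.78e-08). Luminal epithelial genes were lower, with a mean of −0.49 (adjusted p = 0.0111). With an estimated correlation the adjusted p was 0.548, 0.124 and 0.605 for these 3 lists. Repair genes (27 of 37 positive), stress genes (−0.28), interferon genes (−0.50) and class II genes (−0.62) also passed by camera, each with an adjusted p of 0.548 with an estimated correlation. In the blocked fit 1 gene passed, the noncoding RNA Malat1 (−1.77 ± 0.24), and the blocked count ran from 0 to 9 with 1 array or tumor left out. It was above 0 only without the CD29L CD24L array of tumor 1 or 2, the CD29L CD24H array of tumor 2, or all of tumor 1.

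Against CD29L CD24L cells the CD29H CD24H cells had less transcript of immune genes. The T-cell costimulator Icos (−5.08 ± 0.64), the chemokine Ccl5 (−3.79 ± 0.54), Ms4a4b (−3.77 ± 0.53) and P2ry10 (−3.45 ± 0.42) were lower, and these were the 4 genes that passed, 0 higher and 4 lower; P2ry10 was named after its value was seen. The macrophage and myeloid list had 15 of 15 members negative and a mean of −1.31 (camera adjusted p = 1.22e-07; adjusted p = 0.457 with an estimated correlation); 0 members passed over all genes and 1 was lower when adjusted over the list alone. Lists of other kinds moved as well: fibroblast (−0.72, 16 of 17 negative, adjusted p = 0.000754), mesenchymal (−0.62, 0.00725), interferon (−0.67, 0.00234), class II (−0.71, 0.00535) and luminal genes (−0.45, 0.0357) were lower on balance, and mitosis (0.62, 0.000150), DNA replication (0.44, 0.000974) and repair genes (0.28, 0.00725) higher. These had an adjusted p of 0.457 to 0.677 with an estimated correlation. The 2 measured lymphocyte genes had a mean of −2.09 and were not tested as a list. Ptprc, the pan-leukocyte antigen CD45, had a signal of 2982, 2428 and 3316 units in the CD29L CD24L cells of tumors 1, 2 and 7, against 428, 877 and 1028 units in the CD29H CD24H cells. Blocking by tumor passed 58 genes, 13 higher and 45 lower and including those 4, the higher ones including Gtpbp10 (2.12 ± 0.31), the recombination gene Rad51c (2.07 ± 0.37) and Glrb (1.92 ± 0.36), the lower ones S100a9 (−3.41 ± 0.49). The unblocked count was 0 with an offset of 1, 0 with 60% of genes left out, and 0 without the tumor 2 CD29H CD24H array, the tumor 1 CD29H CD24H array, the tumor 1 CD29L CD24L array or any whole tumor. The blocked count was 1 without the first of these arrays, 8 without tumor 1, 10 without the CD29H CD24H array of tumor 7, and 111 without the CD29H CD24L array of tumor 7.

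Averaged over both CD24 gates, CD29 high tumor cells differed from CD29 low cells in matrix and luminal lists, and the matrix difference was larger among CD24 low cells. The fibroblast and collagen list was higher on average, with 17 of 17 positive and a mean of 1.13 (camera adjusted p = 3.24e-15), and the luminal list lower, with a mean of −0.63 (1.98e-06); the macrophage list was lower, with a mean of −0.56 (0.000918). With an estimated correlation the adjusted p was 0.242, 0.242 and 0.655. Adjusted over the list alone, 9 of 17 fibroblast genes were higher. Within CD24 low cells, a setting chosen after seeing the data, the fibroblast list had a mean of 2.59 with 17 of 17 positive (adjusted p = 1.15e-24; 0.0817 with an estimated correlation). Within CD24 high cells its mean was −0.34, with 4 of 17 positive (adjusted p = 0.142). The difference between these gates, which is the interaction given in the next paragraph, passed for 0 genes without the block, and for this list by camera but not with an estimated correlation. Within CD24 low cells 124 genes passed, 119 higher and 5 lower, and 483 with the block. Over both gates no gene passed in limma (0 genes; 705 at an unadjusted p under 0.05), the smallest p belonging to Loxl3 (1.45 ± 0.26), P2ry10 (−1.69 ± 0.30), Il11 (1.63 ± 0.29), Glipr2 (1.33 ± 0.24) and Mrc2, each with an adjusted p of 0.207. With a block by tumor 96 passed, 73 higher and 23 lower, among them 3 fibroblast genes (15 when adjusted over the list alone). The higher ones included tenascin C, Tnc (1.84 ± 0.32), Col14a1 (1.79 ± 0.36) and Bcat1 (1.76 ± 0.29), and the lower ones the antibody genes Jchain (−2.56 ± 0.36) and Igha (−2.21 ± 0.31). This count was 0 without the CD29H CD24H or the CD29H CD24L array of tumor 1, the CD29L CD24H array of tumor 7 or all of tumor 1, 3 without the CD29L CD24H array of tumor 1, 6 without tumor 2, 10 without the CD29H CD24L array of tumor 2, and up to 254 (without the CD29L CD24L array of tumor 7).

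CD24 high tumor cells, averaged over both CD29 gates, had less matrix transcript than CD24 low cells, and most of the matrix difference came from CD29 high cells. The metalloproteinase Mmp3 (−2.64 ± 0.37), Pcolce (−2.76 ± 0.46), Itm2a (−2.73 ± 0.53), Thy1 (−2.14 ± 0.32), Pdgfrb (−2.02 ± 0.41), Fap (−1.94 ± 0.39) and Mmp2 (−1.74 ± 0.32) fell, as did Cdh11 (−2.37 ± 0.44), vimentin, Vim (−1.59 ± 0.31), and Nid1 (−2.07 ± 0.39). Rad51c was the single gene that rose (1.63 ± 0.31). In all 80 genes passed, 1 higher and 79 lower; 5 of 17 fibroblast genes were among them (16 when adjusted over the list alone). The fibroblast list had a mean of −1.85 (camera adjusted p = 2.24e-27; adjusted p = 0.0628 with an estimated correlation), and the mesenchymal list a mean of −1.24 (adjusted p = 0.0229 with an estimated correlation). Macrophage (−0.75, 15 of 15 negative, adjusted p = 2.80e-05), endothelial (−0.61, 0.000963) and interferon genes (−0.50, 0.00201) were lower too, with an adjusted p of 0.353, 0.353 and 0.332 with an estimated correlation. The macrophage difference did not come mostly from CD29 high cells: its mean was −0.64 in these and −0.86 within CD29 low cells (adjusted p = 6.63e-06; 0.701 with an estimated correlation). The difference of the CD24 effect between CD29 high and CD29 low cells was tested as an interaction, in which limma passed 0 genes (646 at an unadjusted p under 0.05) and 211 with the tumor as a block, 20 higher and 191 lower. The fibroblast list had an interaction mean of −2.94 (adjusted p = 4.69e-22; 0.102 with an estimated correlation). Within CD29 low cells, a setting chosen after seeing the data, its mean was −0.38 (adjusted p = 0.0231; 0.829 with an estimated correlation), and its levels in CD24 high and CD24 low cells were 10.62 and 10.85 in tumor 1, 11.97 and 10.83 in tumor 2, and 9.56 and 11.60 in tumor 7. There 2 genes passed, 0 higher and 2 lower, and 10 with the block; of the genes named above, none passed. Over both CD29 gates the blocked fit passed 420 genes, 42 higher and 378 lower and including all 80, and 96 to 438 with 1 array or tumor left out, the lowest without tumor 7. Without the block the count fell to 0 when any of 7 single arrays was left out (the CD29H CD24L array of any of the 3 tumors, the CD29H CD24H array of tumor 2 or 7, or the CD29L CD24H array of tumor 1 or 7), or any whole tumor; it was 1 without the CD29H CD24H array of tumor 1 or the CD29L CD24L array of tumor 7, 9 and 45 without the CD29L CD24L arrays of tumors 2 and 1, and 182 without the CD29L CD24H array of tumor 2. It was 0 without the 2 tumor arrays of lowest actin 3'/5' ratio, an RNA quality measure, in a setting chosen after seeing the data. A higher ratio means more 3' bias, as from degraded RNA, so this setting left out the arrays with the least. Their ratios were 23.2 and 14.4, and those of the other tumor arrays 49.6 to 99.3.

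In normal epithelium the CD29H CD24P cells had the transcripts of basal and myoepithelial cells and the CD29P CD24H cells those of luminal cells. All 18 basal genes were higher in CD29H CD24P cells, with a list mean of 5.89: the contractile genes Myl9 (8.28 ± 0.25), Cnn1 (7.69 ± 0.25) and Myh11 (7.47 ± 0.29), the transcription factor Snai2 (7.35 ± 0.30) and the basal keratin Krt5 (7.17 ± 0.25). Tenm2 (7.65 ± 0.31), Sparc (7.44 ± 0.67), Vcan (7.39 ± 0.37), Serpinb11 (7.36 ± 0.32) and Moxd1 (7.30 ± 0.50) rose likewise. Of 19 luminal genes 16 were lower, among them Ehf (−5.29 ± 0.29), Cldn7 (−5.00 ± 0.26), Krt7 (−4.47 ± 0.26) and Muc1 (−4.09 ± 0.43), and so were all 6 hormone-sensing genes, including Foxa1 (−5.56 ± 0.35), Cited1 (−4.75 ± 0.47), the estrogen receptor gene Esr1 (−4.52 ± 0.27) and the progesterone receptor gene Pgr (−3.58 ± 0.29). Of 12 alveolar and milk genes 7 were lower, with Elf5 at −4.78 ± 0.26 and Aldh1a3 at −4.48 ± 0.25. The largest falls outside the lists were Smim38 (−6.40 ± 0.32), Tesc (−6.20 ± 0.28), Upk3a (−6.16 ± 0.25), Hp (−5.87 ± 0.29), Smim22 (−5.85 ± 0.32), Fgb (−5.69 ± 0.30), Cxcl15 (−5.67 ± 0.31), Rasef (−5.49 ± 0.31) and Tlcd4 (−5.47 ± 0.42).

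Signalling and matrix genes also separated the normal populations. Of 27 Wnt pathway genes 16 were higher in CD29H CD24P cells and 3 lower, with Wif1 at 6.06 ± 0.26, Dkk3 at 4.62 ± 0.27, Nkd1 at 4.10 ± 0.27 and Wnt10a at 3.97 ± 0.43. Of 14 basement membrane genes 10 were higher, including Col4a2 (6.93 ± 0.24) and Col4a1 (4.91 ± 0.20). Of 13 Notch pathway genes 4 were higher, with Dll1 at 5.37 ± 0.25 and Jag2 at 3.47 ± 0.28, and 4 lower, with Notch3 at −3.24 ± 0.24. Of 13 interferon response genes 7 were lower and 1 higher, with Rsad2 at −3.65 ± 0.27. In all 3156 genes passed in limma, 1559 higher and 1597 lower, 2510 of them by at least 1 log2 unit. Of the 21 lists tested 11 passed by camera and 0 with an estimated correlation (adjusted p = 0.199 for the basal, luminal, hormone-sensing and Wnt lists, 0.246 for milk, 0.341 for basement membrane and 0.588 for interferon genes). There were 2 arrays against 2, so that the spread rests on 2 residual degrees of freedom and on what limma borrows across genes. The count was 1913 without the second CD29H CD24P array, 4903 without the second CD29P CD24H array and 855 in a fit of all 17 sorted-cell arrays. The actin 3'/5' ratio was 7.09 and 3.08 in the CD29H CD24P cells and 24.7 and 6.33 in the CD29P CD24H cells.

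The genes of the normal populations were then followed in the tumors, between CD29H CD24H and CD29L CD24H cells. The 1402 measured genes higher in normal CD29H CD24P cells had a mean difference of 0.055, with 795 positive (camera adjusted p = 0.0190), and the 1454 lower ones a mean of −0.17, with 533 positive (adjusted p = 0.0136). With an estimated correlation neither set passed (adjusted p = 0.320 and 0.201). Taking only the 200 genes of smallest p in each direction gave larger means. These were 0.164 with 116 of 174 measured genes positive, and −0.377 with 34 of 162 positive (camera adjusted p = 0.00480 and 3.13e-05). That setting was not run with an estimated correlation. Across 10217 genes, which are not independent replicates, the fold changes of the 2 comparisons had a Spearman rho of 0.133.

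Tumors, as 1 mean per tumor (n = 3), were compared with normal epithelium, as 1 mean per preparation (n = 2). Averaged over the 4 tumor populations, matrix genes were higher than in the normal cells: the collagens Col1a1 (5.70 ± 0.56), Col3a1 (4.89 ± 0.54) and Col1a2 (4.51 ± 0.51), the collagen crosslinking enzyme Lox (5.32 ± 0.40) and Dpt (3.34 ± 0.43) rose, and 14 of 17 fibroblast genes did (15 when adjusted over the list alone). The 2 measured adipocyte genes rose as well, with a mean of 3.78. Of 12 mesenchymal genes 7 rose, including Fn1 (4.08 ± 0.26), Twist1 (3.55 ± 0.56), Zeb1 (2.89 ± 0.41) and Zeb2 (2.71 ± 0.47). Of 15 macrophage genes 7 rose, including C1qb (4.13 ± 0.54) and Csf1r (3.50 ± 0.66), as did the myeloid genes Lyz1 (4.88 ± 0.46), Ms4a6d (4.86 ± 0.59) and Clec4d (4.85 ± 0.49) and the chemokine Cxcl3 (5.01 ± 0.57). Hmga2 (5.17 ± 0.82), Tbx15 (5.02 ± 0.41) and Ccn3 (4.78 ± 0.35) rose too. Of 15 hypoxia and glycolysis genes 4 rose, with Adm at 3.05 ± 0.34 and Ndrg1 at 1.58 ± 0.23. Of 18 basal genes 5 fell, including the oxytocin receptor gene Oxtr (−3.37 ± 0.36), Tagln (−2.86 ± 0.33) and Myh11 (−2.86 ± 0.60). The keratin Krt19 (−5.94 ± 1.08), Fgg (−5.99 ± 0.28), Upk3a (−4.70 ± 0.33), Tlcd4 (−4.34 ± 0.41), Plekhb1 (−4.16 ± 0.50), Tox2 (−4.13 ± 0.60), Fcgbp (−3.74 ± 0.28), Rps15 (−3.57 ± 0.60), AW112010 (−3.47 ± 0.25) and the metallothionein Mt1 (−3.37 ± 0.36) fell, as did Gata3 (−3.28 ± 0.66) and Esr1 (−3.36 ± 0.47), while Ehf rose (4.18 ± 0.30).

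In that comparison 784 genes passed, 466 higher and 318 lower. Aligning the array medians moved the median of all genes by −0.21 and turned the split into 367 higher and 649 lower, so that 36.1% of the calls were higher in place of 59.4%. The count was 0 without either normal preparation, which leaves 1 normal value assumed to vary like the tumors, 352 without tumor 1 and 1534 without tumor 7. Of 21 lists 7 passed by camera and 0 with an estimated correlation (adjusted p = 0.634 for fibroblast, 0.708 for macrophage and basal, and 0.289 for mesenchymal and hypoxia genes). The tumor means take in the CD29H CD24L arrays, whose fibroblast list stood at 13.59 to 13.89, while the normal means leave out the CD24 low array, at 14.41. When CD29H CD24H tumor cells alone were set against normal CD29H CD24P cells, 577 genes passed, 264 higher and 313 lower. The fibroblast list then had a mean of 0.90 in place of 2.65 and did not pass (adjusted p = 0.0580). In this setting Col1a1 (4.82 ± 0.55) and Col3a1 (4.15 ± 0.48) still rose. Col1a2 (3.405 ± 0.51), Col6a3 (3.34 ± 0.52) and Fap (2.26 ± 0.34) passed as higher too, and Dpt did not pass (1.95 ± 0.52, adjusted p = 0.0800). Of the 17 fibroblast genes 7 were negative: Postn (periostin) fell (−2.34 ± 0.38), while Dcn (−2.82 ± 0.75, adjusted p = 0.0799) and Mmp2 (−2.15 ± 0.60, adjusted p = 0.0862) did not pass. The basal list had a mean of −4.13 with 0 of 18 positive (adjusted p = 7.91e-12), in place of −1.12, and the macrophage list still passed with 12 of 14 positive (adjusted p = 0.000392); with an estimated correlation both had an adjusted p of 0.723. There Col4a2, which rose before, stood at −1.59 ± 0.62 (adjusted p = 0.168). The actin 3'/5' ratio was 14.4 to 99.3 on the tumor arrays and 3.08 to 24.7 on the normal ones, so that RNA quality moved with this comparison.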

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

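The tests of other splits in this part were not all planned ahead. For the pairwise comparisons, and for a first form that lumped the remaining arrays into 1 group, the results were seen before a prediction was written. The relabelling of all 4 populations was chosen after that first form had been seen, because it keeps the fit behind the reported counts.

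The effect of the CD29 gate among CD24 high cells differed between tumor and normal tissue in a test of the difference itself, although the gates are not named alike (CD29L CD24H in tumors, CD29P CD24H in normal cells). In limma 272 genes passed, 86 with a higher and 186 with a lower effect in tumors. Of the basal genes 8 passed: Cxcl14 differed by 6.62 between the normal populations and by −0.50 between the tumor ones, and Tagln by 6.73 and 0.55. Krt5 differed by 7.17 and 0.41, but its difference of −6.76 ± 2.73 did not pass (adjusted p = 0.273). The fit behind this test and the 272 genes had no tumor block, so its errors carry the spread between tumors. Krt5 lay between 5.54 and 6.67 on the arrays of tumor 7 and was at least 10.01 in the other tumors. The basal list had a mean difference of −5.70 (adjusted p = 0.0415 with an estimated correlation).

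The single normal CD24 low array entered no comparison between groups. Its fibroblast and collagen genes had a median 5.66 log2 units above the mean of the other 4 normal arrays, higher than all 10000 random lists matched on mean expression (percentile 100), and all 17 were higher. Its macrophage and myeloid genes had a median difference of 0.64 (percentile 98.7), and its luminal genes one of −4.43 (percentile 0). This describes 1 array and has no replicate check.

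Other splits of the samples were counted for each tumor comparison. For CD29H CD24H against CD29H CD24L the real split gave 237 genes and the highest of the other 9 splits gave 0; for CD29L CD24L these were 4 and 0, and for CD29L CD24H 0 and 0. In these comparisons 1, 1 and 10 of the 10 splits gave as many genes, and 10 splits are too few for a share under 0.05. For the first comparison, with 0 genes, all 100 relabellings gave as many, which a real count of 0 fixes beforehand, so that this says nothing about chance. The highest gave 295; that one put the 3 CD29H CD24L arrays in the place of the CD29H CD24H arrays, which points to CD29H CD24L as a population that stands apart. For CD29 high against low, with 0 genes, all 100 gave as many for the same reason, with the highest other at 3. Among the splits that part all 3 tumors as the real one does, the highest counts were 295, 0 and 155 for the first comparison, CD29 and CD24, and 0 in each pairwise comparison. For CD24 high against low 4 of 100 relabellings, the real one included, gave 80 or more, the highest 155. This share is under 0.05, but it holds only for a labelling that mixes all 4 populations and does not exclude chance. In the form with 2 lumped groups the real split gave 0 genes, against up to 289. Of the 3 others, the relabellings with 123 and 81 genes put all 4 arrays of tumor 7 on 1 side, and the blocked count stands in the next paragraph.

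With the tumor as a block and relabelling within tumors, as many genes came from 2 of 100 relabellings for the first comparison (85 genes; the highest other was 532, again with the CD29H CD24L arrays in front), 3 of 100 for CD29 (96; highest other 259) and 1 of 100 for CD24 (420; highest other 230). Each share is under 0.05, but this does not exclude chance. The form was chosen after another had been seen. Mixing the CD29H CD24L arrays into other groups can also raise the spread in the other relabellings and so favour the real one. The form with 2 lumped groups gave 0, 2 and 0 genes for the real split, against up to 547, 5 and 5 for others, and a relabelling that kept the CD29H CD24H arrays and mixed the other 3 populations gave 1 gene in place of 85, so that the blocked counts also depend on keeping the 4 group means.

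The CD29H CD24L arrays were therefore kept in place and the other 3 populations relabelled, a test with its prediction written beforehand; labellings that give the same split were then counted once, after a first run had been seen. With the block and within tumors, as many genes came from 7 of 100 relabellings for the first comparison (85; highest other 141), from 60 of 100 for CD29 (96; highest other 420) and from 1 of 100 for CD24 (420; highest other 415). With those arrays in place, the share for the blocked CD24 count was under 0.05, by a narrow margin (420 against 415). They stayed on the CD24 low side in each relabelling and so enter every count. The 420 genes are therefore not a count apart from them. Within CD29 low cells, where they are not compared, 10 genes passed with the block. That count was 0 without the CD29L CD24H array of tumor 1 or 7, the CD29L CD24L array of tumor 1, or all of tumor 1. It was 1 without tumor 7 and at most 20 in the other settings with 1 array or tumor left out. Chance could not be excluded for the blocked counts of the first comparison and of CD29. Without the block 25 of 100 gave as many as the 80 genes of CD24, so that chance could not be excluded there either; the highest, 849, set tumors 1 and 7 without their CD29H CD24L arrays against the rest, which points to the tumor of origin.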

How the results depend on the processing

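Counts of genes past the threshold moved with several choices, and the cause was not tested except where fewer genes or arrays were used. The settings with the actin 3'/5' ratio and those within 1 gate were chosen after seeing the data. For CD29H CD24H against the other tumor populations (0 genes) the replicate block gave 85 and the block with the actin covariate 122. Against CD29H CD24L (237) the counts were 136 with 60% of genes left out, 398 with each probe set tested, 538 with the block, 450 with block and covariate, and 139 without the 2 arrays of low actin ratio. Against CD29L CD24H (0) they were 1 with the block and 1 with block and covariate. Against CD29L CD24L (4) they were 0 with offset 1, 0 with 60% left out, 58 with the block, 7 with all 17 arrays, 196 with block and covariate, and 2 without the low-ratio arrays. For CD29 (0) they were 96 with the block, 245 with block and covariate, 124 within CD24 low cells and 483 within CD24 low cells with the block. For CD24 (80) they were 41 with offset 1, 131 with an offset 4 times as large, 50 with quantile normalization, 45 with no filter, 49 with 60% left out, 420 with the block, 172 with all 17 arrays, 491 with block and covariate, 0 without the low-ratio arrays, 2 within CD29 low cells and 10 within them with the block. For the normal populations (3156) they were 2088 with 60% left out, 5639 with each probe set and 855 with all 17 arrays. For tumors against normal (784) they were 1821 with each probe set and 1345 with a random block.

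Leaving out 1 array or tumor gave 0 to 1 genes for the first comparison, 0 to 246 against CD29H CD24L, 0 to 0 against CD29L CD24H, 0 to 5 against CD29L CD24L, 0 to 2 for CD29, 0 to 182 for CD24, 1913 to 4903 for the normal populations and 0 to 1534 for tumors against normal.

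Of the 21 lists, those passing were 10, 11, 7, 9, 7, 10, 11 and 7 in the 8 comparisons in the same order. With an estimated correlation they were 0, 3, 0, 0, 0, 1, 0 and 0, and with the replicate block (arrays of the same tumor) and an estimated correlation 0 in each of the 6 tumor comparisons. The replicate block alone gave 11, 11, 8, 9, 7 and 9 lists in the tumor comparisons and 11 in the normal one. The sets of normal genes in the tumors had means of 0.055 and −0.17, and lost their call with an estimated correlation (adjusted p = 0.320 and 0.201) and with the block and an estimated correlation (0.202 and 0.0811). Over the alternatives other than leaving out 1 array or tumor, 187 values of single genes were no longer past the threshold, 32 newly were, and 2231 kept direction and side. These alternatives include the setting without the arrays of low actin ratio and those that compare other gates. With 1 array or tumor left out, 405 were no longer past the threshold, 2 newly were and 1158 kept both. In tumors against normal, Col4a2 reversed to −1.59 (adjusted p = 0.168) when CD29H CD24H tumor cells were set against normal CD29H CD24P cells. The basement membrane list, which had not passed (mean 0.013, adjusted p = 0.979), had a mean of −1.36 there (3.56e-05; adjusted p = 0.494 with an estimated correlation). Within CD24 low cells the mitosis list of the CD29 comparison went from 0.29 to −0.0196 (adjusted p = 0.827, and 0.688 with the block). Within CD29 low cells 3 lists of the CD24 comparison turned: DNA replication from 0.29 to −0.0694 (0.437, and 0.501 with the block), mitosis from 0.33 to 0.0253, below the other genes by camera (0.990 and 0.913), and the stress genes, which had not passed, from −0.079 to 0.307 (0.0218 and 0.0167; adjusted p = 0.701 with an estimated correlation and 0.498 with the block too).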

Other observations

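The tests in this part, of 3 patterns, were chosen after their results had been seen. CD29H CD24L tumor cells stood apart from the other 3 tumor populations by their matrix genes, and tumor 7 differed from tumors 1 and 2 in keratins in all 4 of its populations; that difference rests on 1 tumor and was not tested.

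Fibroblast and collagen genes were lower in CD29H CD24H than in CD29H CD24L cells. A lower share of epithelial cells in the latter, with other cell types in fixed proportion, is argued against by the difference between the fibroblast and macrophage lists, a gap of −2.68 ± 0.23 (SE, n = 3 tumors). RNA degradation followed by the actin 3'/5' ratio is argued against by the list mean of −3.34 with that ratio as a covariate, against −3.32 without it. Fibroblasts sorted into CD29H CD24L may account for the pattern. This was tested on 338 genes outside the lists, taken for standing at least 3 log2 units higher on the normal CD24 low array than on the other normal arrays, at a level of at least 10. Of these 298 were lower in CD29H CD24H in every tumor, against at most 92 in 10000 random sets matched on mean expression. Of the 6 sets tried, this was the widest, and the smallest gave 78 of 82. The random sets were not of genes that move together, so they give no chance level for such a set. The count goes with sorted fibroblasts but cannot tell them from a mesenchymal state. All 17 list members were lower in every tumor, and Col1a1 reached 16760, 30840 and 4753 units in the CD29H CD24L cells of tumors 1, 2 and 7, against 2660, 2402 and 857 in CD29H CD24H; the labels name no gate that would remove them. Of these 17 genes 7 were higher in normal CD29H CD24P than in CD29P CD24H cells, 2 were lower and 8 did not pass, and no other list holds any. A mesenchymal state of tumor cells would bring the same genes and stays open as a biological explanation.

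Mitosis genes were higher in CD29H CD24H than in CD29L CD24H cells in each of the 3 tumors, by 0.52, 0.66 and 0.60. Dilution of the CD29L CD24H cells by non-epithelial cells that do not divide would raise the luminal genes in CD29H CD24H cells as well. They were lower there, and the gap between the lists was 1.08 ± 0.20 (SE, n = 3). But the luminal list also fell with high CD29 among CD24 low tumor cells (mean −0.775) and, for most genes, in normal CD29H CD24P cells. A fall that follows the gate could hide a rise from less dilution, so this test cannot decide. The macrophage list moved as dilution would have it, by −0.45 with 13 of 15 negative (camera adjusted p = 0.0812, and 0.00884 with the block). In tumor 1 it hardly moved (0.027). Dilution, as a part or the whole of the cause, stays open. RNA degradation followed by the actin ratio is argued against by a list mean of 0.55 with the covariate. Other epithelial cells that divide less, and a difference in cycling between the populations, stay open; a candidate explanation is the latter, but the list did not pass with an estimated correlation.

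Cd24a transcript did not differ past the threshold between the CD24 high and low tumor populations. Saturation of its probe set is argued against by the dimmest of its 3 probe sets, which differed by 0.41 ± 0.22, with an upper 95% bound of 0.89, while the same probe set differed by 1.21 between the normal populations. That the CD24 low gate held only the cells of the CD24 high gate is argued against among CD29 high cells, where at least 269 genes differed between the gates in the blocked fit whichever array or tumor was left out. Among CD29 low cells such counts ran down to 0, but the macrophage list argues against it, lower in the CD24 high gate by −0.86 ± 0.13 (SE, n = 3 tumors; camera adjusted p = 9.95e-08 with the block, and 0.255 with an estimated correlation too). The mean of the 11 lymphocyte genes on the array, dim ones left out of the fits included, was 8.06, 7.03 and 7.62 in CD29L CD24L cells of tumors 1, 2 and 7. In CD29L CD24H cells it was 6.31, 6.47 and 6.23. Overlap of a part of the cells was not tested and stays open in both, since fibroblasts or leukocytes in the CD24 low gates could bring these differences.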
